A study of Homo sapiens with 12 samples.

How the data were processed

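RNA was measured on 12 oligonucleotide arrays that interrogate the human transcriptome with 54675 probe sets. The arrays held RNA of MCF10A cells, either wild type (WT) or with eIF4G1 silenced by a doxycycline-inducible short hairpin RNA, each mock-treated or irradiated with 10 Gy. From each of these 4 conditions, 3 RNA preparations were hybridised: a light polysome pool (LMW), a heavy polysome pool (HMW) and total RNA (Total). The sample annotation used here gives ribosome numbers for the WT mock pools only, 1 to 3 per mRNA in LMW and 4 or more in HMW. The other pools carry the same names without numbers. There was 1 array for each condition and preparation. Per the labels' protocols, lysates were sedimented through sucrose gradients after cycloheximide treatment and trypsinisation, and labelled cRNA was made with a 3' in vitro transcription kit.

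The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalises between arrays and summarises probes. The version, and whether all arrays were normalised together, are not given in the sources used here. The values ran from about 4 upwards with none missing, so they were turned to log2 before any comparison. Medians of the deposited intensities lay between 22.6 and 24.4 in the 12 arrays. The number of arrays limits the precision.

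Probe sets were named through the table of the array's annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed. Only those with 1 symbol were used. A gene was represented by its probe set with the highest mean over the 12 arrays, which gave 19775 genes. Genes at a log2 value of at least 6 in at least 4 arrays were kept, 10157 in all. Another probe set of the same gene can read differently, which was tried as an alternative.

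Tests used limma 3.58.1 in R 4.3.3, with moderated variances that follow intensity (eBayes with a trend) and Benjamini-Hochberg adjustment at 0.05. HMW was compared with LMW, and HMW with Total, over 8 arrays each with the condition as a block, so that every condition gave a matched pair. The effects of the knockdown and of 10 Gy were fitted together, without an interaction, on the 4 Total arrays and on the 4 differences HMW minus Total. Those fits leave 1 residual degree of freedom, and for HMW minus Total limma pooled the spread completely over genes. The response to 10 Gy within each genotype, and its difference between genotypes, compare 1 array with 1 and were not tested. For these, genes at or beyond 2-fold (1 on the log2 scale) were counted. A list of genes was placed by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins.

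Gene lists were written before the data were examined: 32 lists with 811 genes, of which 704 were on the array and 633 were kept. Each list was tested against all other genes with limma's camera, with its preset correlation of 0.01 and again with a correlation estimated from the residuals. The second version rests on the residual degrees of freedom, 3 for the fraction comparisons and 1 for the others, so it could hardly call a list. Camera could be run for 29 lists in each comparison. Counts of list members are given over all genes tested and adjusted over the list alone. The designs, the alternatives, the lists and the rule for naming genes were fixed at the same time. The rule names EIF4G1, the 8 genes with the highest and the 8 with the lowest difference among those that pass and go the same way in every pair (by size where there is no test), and in each list described up to 4 members, the 2 highest and the 2 lowest. Members of the repair, damage signalling and survival lists could also be named by size for the difference between genotypes. A gene that the rule also selects is not reported here.

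The scripts were tested on simulated data with 200 genes changed by known amounts. For changes of 2-fold, 93% were recovered for HMW against LMW, 83% for HMW against Total, 99% for the knockdown in Total and 97% for 10 Gy in Total. For HMW minus Total, only 12% were recovered for the knockdown and 19% for 10 Gy, and 82% and 86% of changes of 4-fold. False calls made up 6.13% to 14.0% of the simulated calls. The simulated noise was normal, independent between genes and set to the moderated variance of each fit, so the assumptions of the fit held there. Genes whose pairs spread more than that variance were not represented. These shares check the scripts and need not hold for the real arrays.

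Alternatives were no filter, a filter at 7, the median of all probe sets of a gene, leaving out probe sets that cross-hybridise by their name, a loess correction of each difference, eBayes without a trend, no condition block, each condition left out in turn, all 12 arrays in a single fit with the condition as a random block, and HMW minus LMW in place of HMW minus Total. HMW alone, LMW alone and the irradiated pair alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.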

Results

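MCF10A is generally described as a non-tumorigenic mammary epithelial line, while the labels give its origin as breast cancer. The data consist of 12 arrays, 1 for each combination of genotype (WT or eIF4G1 knockdown), treatment (mock or 10 Gy from a linear accelerator) and RNA preparation (LMW, HMW or Total). The eIF4G1 protein is a scaffold of the cap-binding complex that brings ribosomes to mRNAs. No condition had a replicate, and the time between irradiation and harvest is not given in the sources used here. Nor do they state whether WT cells carried a control hairpin or received doxycycline, so that hairpin, drug and loss of eIF4G1 cannot be separated. All p-values measure only the spread between these samples, since nothing says that they came from separate cultures. In the knockdown and 10 Gy fits the only residual is the difference between the genotypes in the response to 10 Gy. For HMW minus Total in those fits, a gene's own spread between its pairs does not enter its p-value. Differences are on the log2 scale of the deposited intensities, which are relative within each array and carry no measure of total polysome RNA.

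The EIF4G1 transcript was lower in knockdown than in WT cells in all 6 matched comparisons. In Total its intensity was 1027.9 in WT mock and 163.3 in knockdown mock cells, and 864.1 and 176.1 after 10 Gy. Thus 15.9% of the WT level was left in mock and 20.4% in irradiated cells. The largest difference was in HMW of mock cells, where 2901.8 in WT stood against 184.6 in the knockdown. Over the 6 comparisons the mean difference was -2.72, with a range from -3.97 to -1.90. The second EIF4G1 probe set gave a mean of -2.46, with a range from -4.11 to -0.44, and by it 73.6% of the WT level was left in LMW of irradiated cells. Its log2 level was below 6, the filter level for genes, in all 6 knockdown arrays, so these differences are compressed and have no exact size. The related EIF4G2 stayed at 98.8% and 98.7% of WT in Total of mock and irradiated cells, and was at -0.53 in LMW (69.1% of WT) and -0.31 in HMW of irradiated cells.

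**Figure D1:**
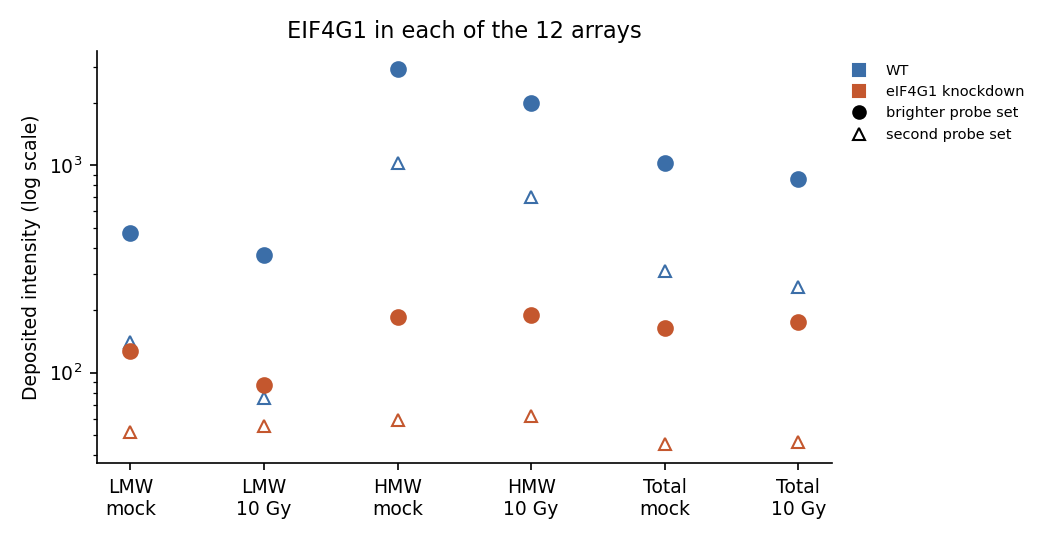
Deposited intensity of EIF4G1 on a log axis in the 12 arrays, by RNA preparation and treatment. Circles are the probe set used throughout and triangles the second one. Every knockdown value lies below its WT counterpart, with 163.3 against 1027.9 in Total of mock cells.

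HMW against LMW asks which mRNAs carry many ribosomes. Most measured mitosis and extracellular matrix genes and all mitochondrially encoded ones were higher in HMW. Among nuclear genes of oxidative phosphorylation more were lower than higher. The number of ribosomes on an mRNA also depends on its coding length, which was not examined. These differences therefore do not measure how efficiently a gene or list is translated. In limma 1991 genes were higher in HMW and 2143 lower, of 10157 tested, and 917 of the higher and 28 of the lower ones were beyond 2-fold. The number of calls fell to 2283 without the WT mock pair and to 2441 without the knockdown mock pair.

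CENPE, a kinesin of the kinetochore, had the largest difference (4.13, adjusted p = 0.000474, higher in 4 of 4 pairs). PRKDC (3.09), HERC1 (3.00), HERC2 (2.97), FRYL (2.96), TPR (2.93) and COL4A1 (2.92) followed, each higher in 4 of 4 pairs. TRIP11 averaged 3.21, but its pairs ran from 0.00498 to 4.65. The lowest were SIVA1 (-1.21), USF1 (-1.19), CTSZ (-1.18), TRAF4 (-1.12), EMP3 (-1.10), MYDGF (-1.09), ERGIC1 (-1.08) and DCAKD (-1.08). CTSZ no longer passed without the WT mock pair (adjusted p = 0.0596) or the WT 10 Gy pair (adjusted p = 0.0546). ERGIC1 no longer passed without the WT mock, the WT 10 Gy or the knockdown mock pair (adjusted p = 0.0737, 0.0921 and 0.112). EIF4G1 itself was higher in HMW (1.68, adjusted p = 0.0106, 4 of 4 pairs). Its pairs ran from 0.54 in mock knockdown to 2.61 in WT mock cells, with both WT pairs above both knockdown pairs.

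Of 20 measured genes for extracellular matrix and adhesion, 14 were higher in HMW and 0 lower, also when adjusted over the list alone (camera adjusted p = 6.11e-08, adjusted p = 0.440 with an estimated correlation). COL4A1 (2.92) and ITGA2 (2.55) were its highest members. Of 34 mitosis genes 19 were higher and 5 lower, and 21 and 5 adjusted over the list alone (camera adjusted p = 4.30e-05, adjusted p = 0.554 with an estimated correlation). CENPF (2.88) was high, whereas BIRC5 (-0.55) and CKS2 (-0.63), which encode small proteins, were low. All 7 mitochondrially encoded transcripts were higher in HMW, also adjusted over the list alone, from ND6 (1.05) and COX1 (1.11) to ATP6 (1.58) and ND2 (2.14) (camera adjusted p = 8.90e-05, adjusted p = 0.652 with an estimated correlation). Mitochondrial ribosomes translate these RNAs, so their place in the gradient is no measure of cytoplasmic translation. Of 63 nuclear genes of oxidative phosphorylation, 26 were lower and 2 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.000570, adjusted p = 0.832 with an estimated correlation). NDUFB7 and ATP5F1D (-0.91) were its lowest members and NDUFS1 (1.02) its highest. Among 26 homologous recombination genes 15 were higher and 5 lower, and 16 and 5 adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.652 with an estimated correlation). RAD50 (2.67) and WRN (2.05) were its highest and MUS81 (-0.71) and FANCE (-0.72) its lowest members. With the preset correlation 9 of the 29 lists were called here. No list call in any comparison was kept with an estimated correlation, where the lowest adjusted p was 0.409. With 3 or 1 residual degrees of freedom that version could hardly call any list, so it does not decide about them. The preset version takes list members as nearly independent. Its p-values can therefore be far too small for genes that move together, and they rank lists rather than measure evidence.

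HMW against Total asks which mRNAs are on heavy polysomes relative to their abundance in the cell. Most replication and proteasome genes, and many of mitosis and base excision repair, were over-represented on heavy polysomes. Most ribosomal protein mRNAs were under-represented. In limma 1763 genes were higher in HMW and 1894 lower, with 448 and 864 beyond 2-fold. The number of calls was 1659 without the WT 10 Gy pair and 2286 without the knockdown mock pair.

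FOS had the largest fitted excess in heavy polysomes (3.09, adjusted p = 0.000690, higher in 4 of 4 pairs). MAD1L1 (2.48), NCAPD2 (2.45), PFAS (2.36), IPO4 (2.32), GEMIN4 (2.16) and MAP3K6 (2.04) followed, each in 4 of 4 pairs. MMP1 (2.75) passed with pairs from 0.50 to 5.29, the larger ones in knockdown cells, and no longer did so without the knockdown mock pair (adjusted p = 0.0789). It lay below the filter level of 6 in every Total array, so its excess has no exact size and cannot be ranked against that of FOS. The nuclear RNA MALAT1 (-6.47, adjusted p = 5.32e-06, lower in 4 of 4 pairs), GOLGA8A (-5.43), FTX (-5.34), ANKRD36B (-4.64), UTRN (-4.33), RUSC1-AS1 (-4.14) and LOC100190986 (-3.92) had large deficits. All 7 lay below the filter level of 6 in every HMW array, where differences are compressed, so their deficits have no exact size and no order. EIF4G1 did not pass (0.75, adjusted p = 0.0628), but did so without the knockdown 10 Gy pair (0.96, adjusted p = 0.0401). Its pairs ran from 0.10 in irradiated knockdown to 1.50 in WT mock cells, with both WT pairs above both knockdown pairs. The fitted value thus averages a larger excess in WT with little in the knockdown.

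Of 35 replication genes 27 were higher on heavy polysomes and 0 lower, and 29 adjusted over the list alone (camera adjusted p = 4.59e-11, adjusted p = 0.409 with an estimated correlation). MCM2 (2.04) and MCM5 (1.94) led, while SLBP was at 0.02. Of 34 mitosis genes 16 were higher, and 17 adjusted over the list alone, with CDC20 at 1.95 and KIF2C at 1.90 (camera adjusted p = 1.07e-05, adjusted p = 0.697 with an estimated correlation). Of 27 proteasome genes 16 were higher, and 17 adjusted over the list alone, with PSMC4 (0.94) and PSMC3 (0.86) on top (camera adjusted p = 1.81e-05, adjusted p = 0.697 with an estimated correlation). Of 22 base excision repair genes 11 were higher, and 13 adjusted over the list alone, with LIG1 (1.44) and XRCC1 (1.08) the highest (camera adjusted p = 0.00171, adjusted p = 0.697 with an estimated correlation). Of 52 ribosomal protein genes 35 were lower and 2 higher, and 35 and 3 adjusted over the list alone (camera adjusted p = 8.08e-09, adjusted p = 0.697 with an estimated correlation). RPS12 (-1.07) and RPL36 (-0.92) were the lowest, RPLP2 (0.69) and RPL27A (0.68) the highest. Of 4 nuclear non-coding RNAs 3 were lower, with TUG1 at -1.94, and MEG3 was higher (0.62), also adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.697 with an estimated correlation). In all 12 lists were called with the preset correlation.

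The knockdown in total RNA asks how cells with little eIF4G1 differ in mRNA abundance. Nearly all measured replication and mitosis genes fell, and so did most of homologous recombination and sterol synthesis. Most interferon-stimulated genes, p53 targets and ribosomal protein genes rose. In limma 2100 genes rose and 2013 fell in the knockdown, and beyond 2-fold 157 rose and 433 fell. The 4113 calls became 2692 with the median of probe sets and 2373 over all 12 arrays. The fit assumes the same knockdown effect in mock and irradiated cells, and 2 pairs stand behind each value.

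IL24 (3.12), ISG15 (2.69), IFI6 (2.67), ZNF91 (2.49), IL13RA2 (2.32), DDX60 (2.27), H1-2 (2.23) and TPRG1 (2.23) rose most, in 2 of 2 pairs each. DCN, which encodes the matrix protein decorin, fell by 3.36 (adjusted p = 1.27e-06, 2 of 2 pairs), but it was higher in the knockdown in both polysome pools, and the fit over all 12 arrays gave 0.91 (adjusted p = 0.532). BIRC5 (-2.96), ALOX5AP (-2.86), LTBP1 (-2.85), TMT1A (-2.68), MRGPRX3 (-2.57), MND1 (-2.57) and TAGLN (-2.56) fell as well. TAGLN no longer passed when probe sets of its kind were left out (-0.13, adjusted p = 0.589). EIF4G1 fell by 2.47 (adjusted p = 2.26e-06, 2 of 2 pairs).

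All 34 mitosis genes fell, with a median of -2.02, also adjusted over the list alone (camera adjusted p = 2.90e-20, adjusted p = 0.626 with an estimated correlation). They ran from BIRC5 (-2.96) and MKI67 (-2.46) to ESPL1 (-1.45) and PLK1 (-1.31). For all 34 the knockdown value was lower in irradiated than in mock cells, with a median difference of 1.19. The same held for 34 of 35 replication genes, with a median difference of 0.66 over the list. The shared effect that the fit assumes is thus only an average for these lists. Their estimated correlations were 1 for mitosis and 0.89 for replication, each from 1 residual degree of freedom, against the preset of 0.01. That of p53 targets was 0.004. The preset p-values of the mitosis and replication lists therefore cannot be taken at their size. Of 35 replication genes 33 fell and 0 rose, also adjusted over the list alone, with CDC6 (-2.07) and GINS2 (-2.07) the lowest (camera adjusted p = 5.88e-18, adjusted p = 0.626 with an estimated correlation). All 9 genes for the sliding clamp, its loader and the single-strand binding complex fell, also adjusted over the list alone, RFC3 (-1.49) and RFC5 (-1.41) most (camera adjusted p = 3.13e-06, adjusted p = 0.626 with an estimated correlation). Of 26 homologous recombination genes 21 fell and 2 rose, and 22 and 2 adjusted over the list alone (camera adjusted p = 1.55e-07, adjusted p = 0.626 with an estimated correlation). BRIP1 (-1.83) and RAD54B (-1.81) fell most, and RAD50 (0.42) and MUS81 (0.37) rose. Of 19 sterol synthesis genes 11 fell and 0 rose, and 12 fell adjusted over the list alone, HMGCS1 (-1.45) and ACAT2 (-1.14) most (camera adjusted p = 0.000126, adjusted p = 0.626 with an estimated correlation). Of 10 mesenchymal genes 7 fell and 2 rose, also adjusted over the list alone, with FBN1 at -1.29 and ACTA2 at 0.93 (camera adjusted p = 0.00689, adjusted p = 0.626 with an estimated correlation).

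Of 21 interferon-stimulated genes 14 rose and 1 fell, also adjusted over the list alone, from ISG15 (2.69) and IFI6 (2.67) to IFITM1 (-0.75) (camera adjusted p = 7.77e-05, adjusted p = 0.626 with an estimated correlation). Of 32 p53 targets 20 rose and 4 fell, and 21 and 4 adjusted over the list alone (camera adjusted p = 0.000282, adjusted p = 0.626 with an estimated correlation). PMAIP1 (1.35) and CDKN1A (1.08) rose most and KITLG (-1.30) fell most. Of 52 ribosomal protein genes 28 rose and 0 fell, and 29 rose adjusted over the list alone, by small amounts up to 0.33 for RPL38 (camera adjusted p = 3.13e-06, adjusted p = 0.626 with an estimated correlation). Of 38 initiation factor genes 19 rose and 2 fell, and 20 and 2 adjusted over the list alone, with EIF3G at 0.76 and EIF4EBP1 at -0.66 (camera adjusted p = 0.00207, adjusted p = 0.626 with an estimated correlation). With the preset correlation 14 lists were called.

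**Figure D2:**
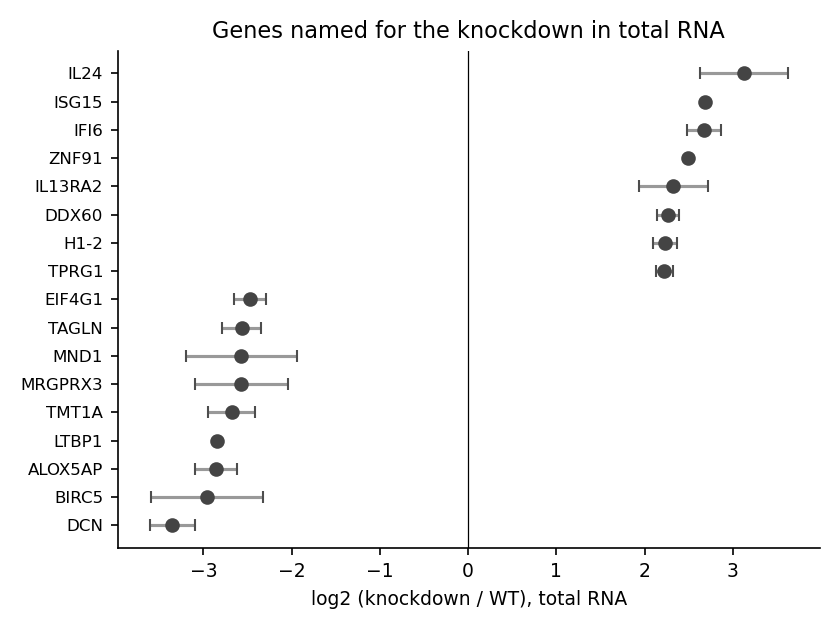
Difference between knockdown and WT in total RNA (log2) for the genes named by the rule. Points are the fitted effects and bars span the 2 matched pairs, mock and 10 Gy. IL24 stands highest at 3.12 and DCN lowest at -3.36.

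The knockdown in HMW relative to Total asks which mRNAs gained or lost ribosome association without eIF4G1. Some extracellular matrix, mitosis and basal epithelial genes were higher on heavy polysomes relative to Total in the knockdown, and none of these lists had a member that passed downwards. Mitosis genes averaged -2.02 in Total and 0.99 in HMW minus Total, so in HMW itself they were lower on average in the knockdown. Their gain is only relative to a larger fall in Total. Interferon-induced IFI6 and ISG15 were lower relative to Total, where they rose, but not in HMW itself (0.16 and 1.08). DCN, MMP1, ID2, MMP10 and S100P, among the largest gains, were at least 4-fold higher in every polysome array of knockdown cells, LMW included, than in their Total arrays, so HMW minus Total is no measure of ribosome loading alone for them. In limma 288 genes were higher and 46 lower. These 334 calls became 623 without a filter, 220 with the median of probe sets and 196 without _x_at and _s_at probe sets. They became 1354 in HMW minus LMW and 1006 in HMW alone. The mock pair alone had 2456 genes beyond 2-fold and the irradiated pair, which leaves out the WT mock arrays, 453.

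DCN had the largest value (6.18, pairs 6.16 and 6.19). Its log2 level was 10.1 in Total and 6.22 in HMW of WT mock cells, and 7.05 and 9.29 in mock knockdown cells. SERPINB3 (4.51), MMP1 (4.35), ID2 (3.99), MMP10 (3.88), S100P (3.79), SLC7A2 (3.68) and HSD17B2 (3.59) were also high, in 2 of 2 pairs each. MMP1, ID2 and MMP10 lay below the filter level of 6 in every WT array and in both Total arrays of knockdown cells, so their values have no exact size and no order. DCN, SERPINB3, ID2 and HSD17B2 were below 0 when HMW was set against LMW. The log2 level of ID2 in mock knockdown cells was 4.91 in Total, 9.33 in LMW and 8.95 in HMW. In WT mock cells it was 5.14, 5.19 and 5.12. IFI6 (-2.51, adjusted p = 0.00306, 2 of 2 pairs) and ISG15 (-1.61, adjusted p = 0.0202, 2 of 2 pairs) were low, as were TUBAL3 (-2.02), MEX3D (-1.83), MMP9 (-1.69), FOLR1 (-1.62), INSC (-1.62) and HES4 (-1.59). TUBAL3 and INSC lay below 6 in every knockdown array, so the same holds for them. In HMW alone IFI6, MMP9 and ISG15 lay above 0, and HES4 did so against LMW. The log2 level of IFI6 in HMW was 5.61 in WT and 5.80 in knockdown mock cells, below the filter level of 6, and little above it after 10 Gy, so its value has no exact size and a loss from heavy polysomes cannot be read from it. EIF4G1 was low too (-1.22, adjusted p = 0.0212, 2 of 2 pairs), but did not pass with a loess correction (adjusted p = 0.0524).

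Of 20 extracellular matrix genes 8 passed upwards and 0 downwards, and 14 adjusted over the list alone, FN1 (3.42, pairs 3.21 and 3.62) and ITGA2 (3.07, pairs 1.77 and 4.36) most (camera adjusted p = 3.78e-14, adjusted p = 0.806 with an estimated correlation). Of 34 mitosis genes 12 passed upwards and 0 downwards, and 17 adjusted over the list alone (camera adjusted p = 3.76e-17, adjusted p = 0.806 with an estimated correlation). CENPE (3.01, pairs 1.71 and 4.30) and CENPF (2.84, pairs 2.35 and 3.32) were highest and PLK1 (-0.38) lowest. Of 12 basal epithelial genes 4 passed upwards, and 6 adjusted over the list alone, DSC3 (3.12, pairs 1.68 and 4.57) and DSG3 (2.97, pairs 2.05 and 3.89) most (camera adjusted p = 3.91e-08, adjusted p = 0.806 with an estimated correlation). Of 11 luminal epithelial genes 3 passed upwards, and 4 adjusted over the list alone, ELF3 (2.47) and MUC1 (1.79) most (camera adjusted p = 0.0109, adjusted p = 0.806 with an estimated correlation). ELF3 lay below 6 in every WT array and in Total of knockdown cells. The larger value of each pair given for ITGA2, CENPE, CENPF, DSC3 and DSG3 is that of mock cells, which includes the WT mock arrays.

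**Figure D3:**
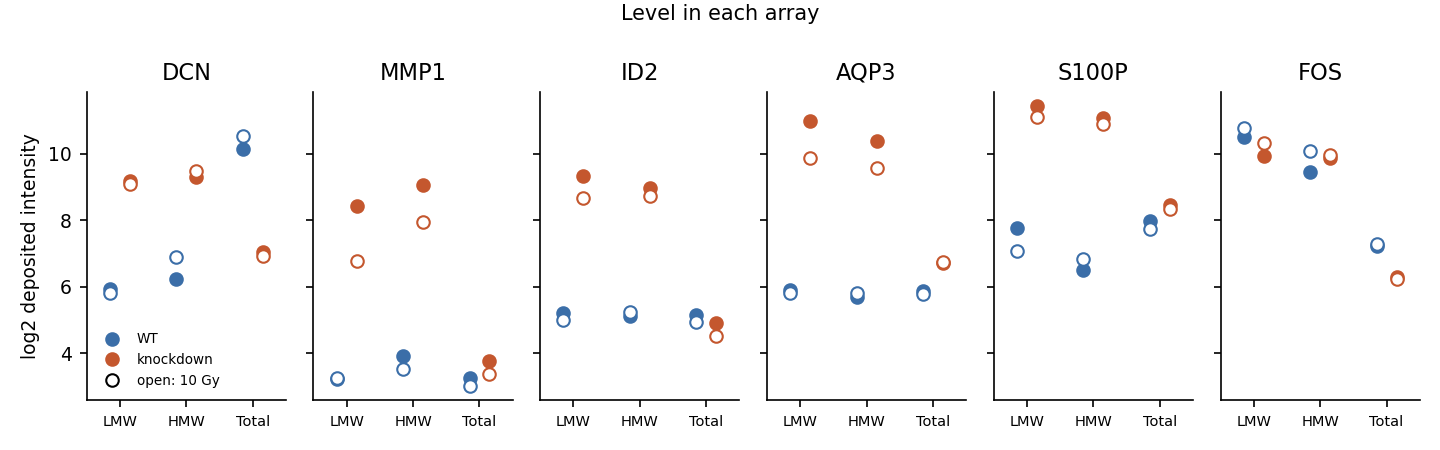
Level (log2 deposited intensity) of 6 genes in each of the 12 arrays, by RNA preparation. Filled points are mock and open points 10 Gy. ID2 in mock knockdown cells is at 4.91 in Total and 9.33 in LMW, while DCN of WT mock cells is at 10.1 in Total and 5.94 in LMW.

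The effect of 10 Gy in total RNA asks which transcripts irradiation changed in both genotypes. Few genes passed. The genes that rose include a few p53 targets, and those that fell include MCM6 of the replication helicase. In limma 13 genes rose and 5 fell, while 1305 had an unadjusted p below 0.05. The 18 calls became 46 with a filter at 7, 39 without a filter and 6 with the median of probe sets. They became 6 without _x_at and _s_at probe sets and 2 over all 12 arrays. In limma without a variance trend there were 0, where 1146 had an unadjusted p below 0.05.

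SUGCT (1.17, adjusted p = 0.00997), TRIM22 (1.17, adjusted p = 0.0119), GDF15 (1.05, adjusted p = 0.0274), GASK1B (0.95), the histone gene H2AC6 (0.93), DAPK1 (0.89), TP53INP1 (0.86) and the histone gene H2BC5 (0.78) rose in 2 of 2 pairs each. FGFBP1 (-1.18, adjusted p = 0.00656), the replication helicase gene MCM6 (-1.02), PEG10 (-0.79), H2AX (-0.71) and TRMT5 (-0.51) fell in 2 of 2 pairs each. H2AX no longer passed with the median of its probe sets (-0.16, adjusted p = 0.771). EIF4G1 did not pass (-0.07, adjusted p = 0.856).

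Of 32 p53 targets 4 rose and 0 fell, and 18 rose adjusted over the list alone (camera adjusted p = 1.08e-22, adjusted p = 0.637 with an estimated correlation). Of 35 replication genes 0 rose and 1 fell, and 26 fell adjusted over the list alone (camera adjusted p = 9.07e-21, adjusted p = 0.637 with an estimated correlation). Its lowest members, CDC6 at -1.25 (-0.53 in WT and -1.96 in the knockdown) and MCM10 at -1.20 (-0.60 and -1.79), did not pass over all genes. Of 34 mitosis genes 0 passed over all genes in limma, and 28 fell adjusted over the list alone (camera adjusted p = 4.71e-15, adjusted p = 0.637 with an estimated correlation). That fall lay in the knockdown pair: the median of the list was -1.18 there and -0.03 in WT, where HMMR stood at 0.82. Of 26 homologous recombination genes 0 passed, and 7 fell adjusted over the list alone, with EXO1 at -1.15 (-0.65 in WT and -1.66 in the knockdown) and BLM at -0.82 (-0.15 and -1.50) (camera adjusted p = 2.70e-08, adjusted p = 0.637 with an estimated correlation). With the preset correlation 16 lists were called, several of them with medians near 0.

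The effect of 10 Gy on HMW relative to Total asks which mRNAs moved onto or off heavy polysomes after irradiation in both genotypes. It left 3 genes in limma, all higher, and 664 had an unadjusted p below 0.05. The same fit recovered 19% of simulated changes of 2-fold. The 3 calls became 26 without a variance trend, 16 without a filter, 1 with a filter at 7, 1 with a loess correction and 0 in limma with the median of probe sets, where 421 had an unadjusted p below 0.05. The 3 genes were TRIP11 (1.74, adjusted p = 0.00796, pairs 0.61 and 2.86), SERPINB3 (1.74, adjusted p = 0.00796, 2 of 2 pairs) and CENPI (1.59, adjusted p = 0.0173, 2 of 2 pairs). SERPINB3 was at -0.082 when HMW was set against LMW. Of 26 homologous recombination genes 0 passed over all genes, and 6 were higher adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.905 with an estimated correlation). Its highest members were RAD50 at 1.35 (pairs 0.27 and 2.43) and BRIP1 at 1.34 (pairs 0.49 and 2.20), each with the larger value in WT.

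Within each genotype, the response to 10 Gy asks whether eIF4G1 changes how cells redirect translation after damage, the question in the title of the series. In WT cells many mRNAs stood higher in both polysome pools after 10 Gy, while few differed in total RNA. In knockdown cells few mRNAs differed in the polysome pools, while mitosis genes had medians below all random lists in total RNA and in both pools. Each value compares 1 array with 1, without a replicate check.

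In WT cells 1607 genes were at least 2-fold higher and 223 lower after 10 Gy in HMW, 1620 and 421 in LMW, and 8 and 1 in Total. In knockdown cells 34 were higher and 52 lower in HMW, 23 and 112 in LMW, and 2 and 96 in Total. For HMW minus Total, 1678 genes were higher and 173 lower in WT, and 50 and 7 in the knockdown. With a loess correction the share of higher genes went from 90.7% to 79.9% in WT and from 87.7% to 77.6% in the knockdown. The spread of HMW minus Total over genes was 1.11 (SD) in WT mock cells, against 0.70 in irradiated WT, 0.70 in mock knockdown and 0.66 in irradiated knockdown cells.

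**Figure D4:**
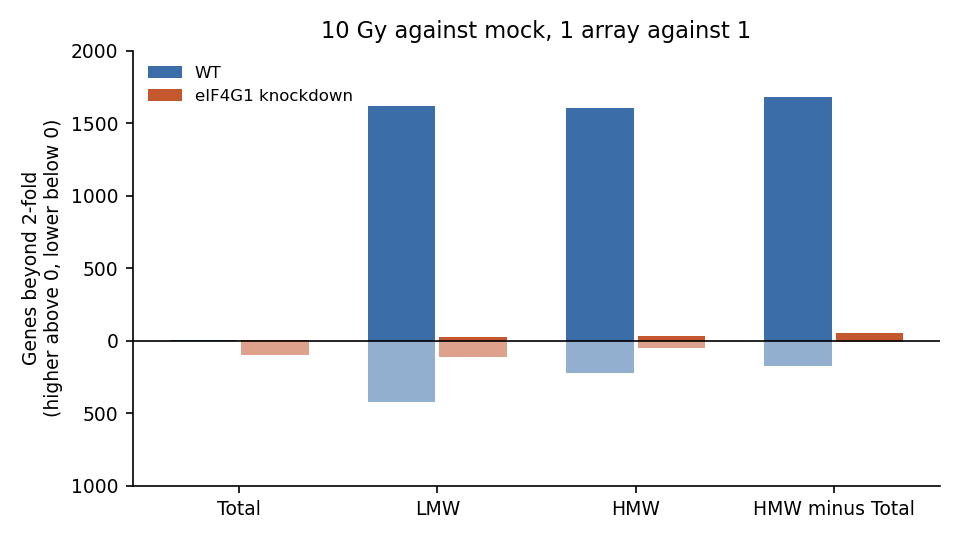
Number of genes at least 2-fold higher (above the zero line) or lower (below it, paler) after 10 Gy, by RNA preparation and genotype. WT cells have 1607 higher genes in HMW and knockdown cells 34, while Total has 8 and 2.

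The highest WT values of HMW minus Total belonged to ZNF292 (3.51), FAM98B (3.51), EHF (3.31), RBBP6 (3.30), HYCC2 (3.22), EEA1 (3.21), MAP9 (3.20) and BDP1 (3.19). The lowest were PLPP4 (-1.79), H2BC6 (-1.69), SLC6A2 (-1.62), LINC01003 (-1.62), SMO (-1.62), SP8 (-1.59), H1-2 (-1.54) and TAMALIN (-1.52). In knockdown cells TMT1A (1.66), CARD16 (1.62), CFAP300 (1.51), KLRK1-AS1 (1.46), DEPDC7 (1.45), CLK1 (1.43), SERPINB3 (1.36) and GINS4 (1.32) were highest. The lowest named there were MIF-AS1 (-1.31), MAP4K5 (-1.22), ITGA8 (-1.09) and TMPRSS2 (-1.04). In Total of WT cells TRIM22 (1.42), SUGCT (1.35), GDF15 (1.35), TREM2 (1.14), IL24 (1.06) and SPATA18 (1.01) were highest and FGFBP1 (-1.20) lowest. In Total of knockdown cells GAS2L3, CDC6 (-1.96), KIF20A (-1.86), MCM10 (-1.79), SGO2 (-1.78), PSRC1 (-1.67), EXO1 (-1.66) and CDC20 (-1.65) were lowest.

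Mitosis genes had a median of -1.18 after 10 Gy in Total of knockdown cells, below all 10000 random lists, and 25 of the 34 were at least 2-fold lower. In WT the median was -0.03, at percentile 51.1. In the polysome pools of knockdown cells it was -0.86 in HMW and -0.92 in LMW. In WT cells it was 0.54 in HMW, but 0.13 in LMW, at percentile 63.6. Replication genes had a median of -0.92 in Total of knockdown cells, with 15 of 35 at least 2-fold lower, and -0.20 in WT, below all random lists in both. In the pools the median was -0.73 in HMW and -0.89 in LMW of knockdown cells, and -0.25 in HMW (percentile 2.36) and -0.54 in LMW (percentile 0.03) of WT cells, where 15 and 14 of the 35 lay above 0. In LMW of WT cells 8 of 35 were at least 2-fold lower. Homologous recombination genes stood at -0.56 in Total of knockdown and -0.16 in Total of WT cells. Targets of p53 were higher in Total of both genotypes, by a median of 0.36 in WT and 0.29 in the knockdown.

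**Figure D5:**
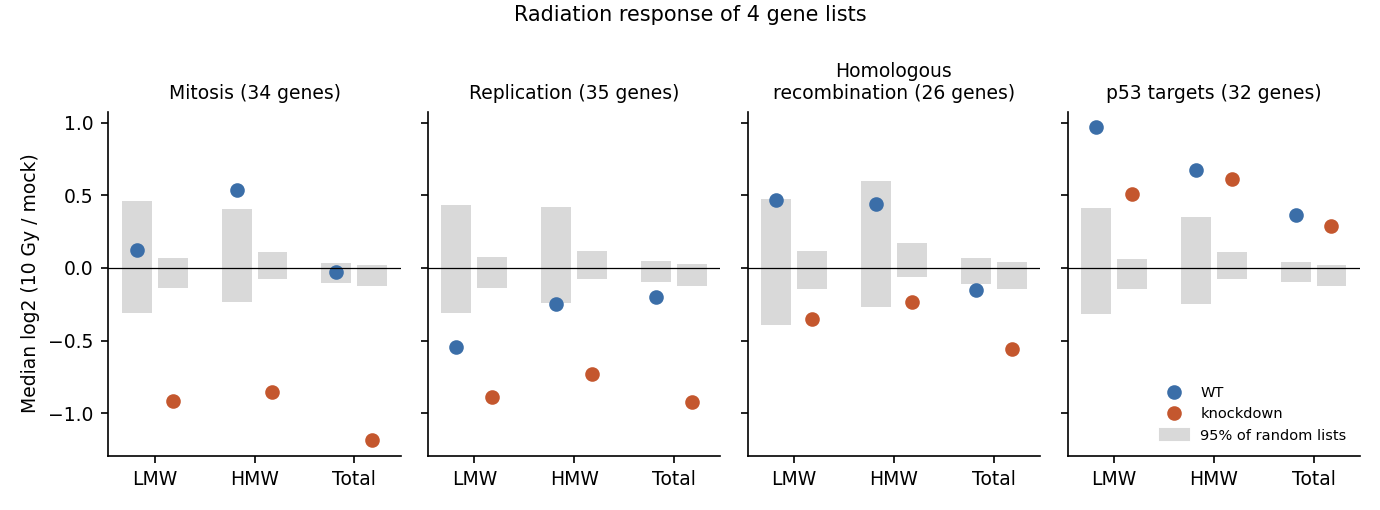
Median change after 10 Gy (log2) of 4 gene lists, by RNA preparation and genotype, with grey bars for the central 95% of random lists. Mitosis genes lie at -1.18 in Total of knockdown cells and at -0.03 in WT.

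On heavy polysomes relative to Total, homologous recombination genes of WT cells had a median of 0.57 after 10 Gy, at percentile 96.7, and 9 of 26 were at least 2-fold higher. In knockdown cells the median was 0.39, above all random lists, while the list median was -0.23 in HMW itself and -0.56 in Total. Nucleotide excision and mismatch repair genes of WT cells had a median of 0.73 (percentile 99.7), with 7 of 21 at least 2-fold higher, ERCC4 (2.41) and ERCC5 (1.85) most. In knockdown cells that median was 0.17 (percentile 85.3). Targets of p53 had medians of 0.45 in WT (percentile 98.96) and 0.29 in the knockdown (percentile 99.99). Mitosis genes had medians of 0.51 in WT (percentile 99.26) and 0.34 in the knockdown, above all random lists, with 29 of 34 above 0 there, and the difference had a median of 0.18 (percentile 85.4). Survival genes stood at 0.10 in WT, at percentile 62.4. Base excision repair genes stood at -0.04 in WT, at percentile 24.1. Every WT value here rests on the single WT mock HMW array, and after the part that followed the HMW minus LMW difference of knockdown cells was taken out, 23.01% of the 1830 genes beyond 2-fold in HMW of WT cells were still so. The lists were not examined after that step.

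The radiation response of WT minus that of the knockdown, in HMW minus Total, was at least 1 for 1572 genes and at most -1 for 504. In Total alone it was so for 81 and 7. RBBP6 (3.42), FAM98B (3.39), MAP4K5 (3.34), EHF (3.18), INHBA (3.14), CLCA2 (3.04), CHML (3.03) and BDP1 (3.02) had the highest differences. INHBA was at 1.39 with the median of its probe sets. IQGAP3 (-2.58), LINC01003 (-2.18), H2BC6 (-2.05), HHAT (-2.02), GBF1 (-1.90), COL1A1 (-1.89), CLUHP3 (-1.87) and PLPP4 (-1.85) had the lowest. COL1A1 was at 0.41 with the median of its probe sets. EIF4G1 had a difference of -0.21.

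Repair and survival genes lay on both sides. RFC1 (2.19), RAD50 (2.16), TDG (2.04), NBN (1.93), BRIP1 (1.70), TOPBP1 (1.49), CHEK1 (1.40), XIAP (1.29) and ATR (1.11) were among those that responded more in WT. The WT response of RAD50 was 2.43 and the knockdown response 0.27. MPG (-1.30), RMI2 (-1.20), FANCG (-1.14), BCL2L1 (-1.10) and EME1 (-1.05) had lower responses in WT than in the knockdown. As lists they did not stand apart from random ones in HMW minus Total: homologous recombination had a median difference of 0.06 (percentile 62.3), nucleotide excision and mismatch repair 0.36 (percentile 94.1), damage signalling 0.28 (percentile 88.6), base excision repair -0.08 (percentile 35.5), end joining 0.22 (percentile 76.8), clamp loading -0.07 (percentile 43.4) and survival -0.11 (percentile 39.0). Pro-apoptotic genes stood lower in HMW minus Total, with a median of -0.54 at percentile 0.29. Heat shock genes stood higher, with 0.65 at percentile 99.3. Both values rest on the single WT mock HMW array. Both lists ran the same way in HMW against LMW, where 10 of 23 pro-apoptotic genes were lower and 2 higher. Of 11 heat shock genes 7 were higher there and 2 lower. Fractions pooled differently for WT mock cells thus cannot be told apart from an effect of eIF4G1. In HMW itself the median difference was 0.64 for homologous recombination (percentile 98.96), 0.46 for replication (percentile 98.72) and 1.35 for mitosis (above all random lists). In Total it was 0.66, 0.66 and 1.19, above all random lists for each.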

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

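All tests in this part were chosen in their present form after the results were seen.

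In the RNA preparations named below, the response to 10 Gy ran in opposite directions in the genotypes, beyond the central 95% of random lists in both, for 2 gene lists, and by at least 2-fold in both for 3 of the named genes. None of these differences was tested. Other lists had medians of opposite sign that met this in at most 1 genotype, among them homologous recombination in LMW (0.47 in WT, percentile 97.4, and -0.35 in the knockdown, percentile 0). Mitosis genes in HMW had a median of 0.537 in WT, with 24 of 34 above 0, and of -0.86 in the knockdown, with 0 of 34. In LMW the median was 0.13 in WT, within the random range at percentile 63.6, and -0.92 in the knockdown. Their median in Total of the knockdown was -1.18, and in HMW minus Total it was above 0 in both genotypes, at 0.51 in WT and 0.34 in the knockdown. Mitochondrially encoded transcripts in LMW had a median of -0.4172 in WT and 0.16 in the knockdown. In HMW minus Total the difference between genotypes was 3.344 for MAP4K5 (2.13 in WT and -1.22 in the knockdown) and -2.575 for IQGAP3 (-1.34 and 1.24). In Total alone the values were -0.55 and 0.57 for MAP4K5, and 0.29 and -0.71 for IQGAP3. The knockdown value of MAP4K5 was -0.19 with the median of its probe sets. In HMW the difference was 3.53 for CENPE (2.5 and -1.03). Its knockdown response was -1.07 in Total and 0.04 in HMW minus Total.

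Only 8 splits of the 8 arrays part all 4 matched pairs, too few for a share under 0.05. For HMW against LMW the real one, 1 of the 8, gave 4134 genes and the highest other 0. For HMW against Total the real one, again 1 of the 8, gave 3657 genes and the highest other 0.

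The polysome pools of WT cells shifted after 10 Gy, and those of knockdown cells changed much less. A smaller amount of RNA on the WT mock arrays is argued against: the HMW pair of knockdown cells differed more in spiked control RNA (-1.01) than the WT pair (-0.63), yet had 86 genes beyond 2-fold against 1830. Gradient fractions pooled differently for the WT mock culture may account for much of it. After the part that followed the HMW minus LMW difference of knockdown cells was taken out, 23.01% of the 1830 genes (421) still lay beyond 2-fold, and 38.0% did so in LMW. Movement of mRNAs by radiation cannot be told apart from this, with 1 WT mock array per pool. More degraded RNA in the WT mock pools would raise the 3' to 5' ratios of control transcripts, and these gave no sign of it. The GAPDH ratio was at most 1.246 there and at least 1.32 in the other polysome arrays. That of ACTB was 2.40 to 2.42 there, within the 2.30 to 3.42 of the others. Only 2 control transcripts read it, so more degradation stays open.

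In knockdown cells 9 genes were at least 4-fold higher in every polysome array than in either Total array, against 1 gene in WT, which was FOS and was also among the 9. At 8-fold, the threshold tried first, there were 3 against 0. These counts take only genes higher in polysomes. In the other direction, DCN of WT cells was at 10.1 and 10.5 in Total and at most 6.89 in the polysome arrays. Such disagreement is thus not limited to knockdown cells. The 9 genes had a median log2 level of 5.802 in WT polysomes and 9.14 in knockdown polysomes, the latter high by selection. For 8 of them, all but FOS, every WT polysome array lay below every knockdown one. For these, probe sets that read RNA of other genes in the polysomes of both genotypes are argued against. RNA of other genes present only in knockdown polysomes cannot be excluded. Polysome and total RNA from cultures in different states are a candidate explanation, and the labels name no biological counterpart beyond enrichment on ribosomes. That enrichment cannot be told apart from it, since the median level in Total of knockdown cells was 5.956, about the filter level of 6, with S100P (8.44), DCN (7.05), AQP3 (6.71), FOS (6.28) and SPRR1B (6.14) above it in mock cells.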

How the results depend on the processing

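HMW alone, LMW alone and the irradiated pair were chosen after the result was seen. The labels give no replicate numbers to pair by. HMW was paired with LMW and with Total by condition, and the fit without that block is given here. In each case the cause was not tested, except where fewer arrays or genes entered the fit.

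Of 693 values of named genes with a test, 601 kept direction and side of the threshold, 79 no longer passed, 2 newly passed, 1 moved and 10 reversed. Of 556 without a test 533 stayed within 1 median absolute deviation over genes, 22 moved and 1 reversed. The mean EIF4G1 difference over the matched comparisons held with the second probe set and with each array centred on its median. A loess correction moved the median of all genes by up to 0.19.

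For HMW against LMW the 4134 calls became 55 without the condition block and 2283 to 4593 with a condition left out. For HMW against Total the 3657 became 2321 without _x_at and _s_at probe sets and 1659 to 4496 with a condition left out. For the knockdown in Total the 4113 became 2692 with the median of probe sets and 2373 over all 12 arrays, where DCN reversed to 0.91 (adjusted p = 0.532).

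For the knockdown in HMW minus Total the 334 calls became 623 with no filter and 220 with the median of probe sets. They became 196 without _x_at and _s_at probe sets, 1354 in HMW minus LMW and 1006 in HMW alone. In HMW minus LMW DCN (-0.45), SERPINB3 (-0.63), ID2 (-0.25), HSD17B2 (-0.40) and HES4 (0.21) reversed, none past the threshold. In HMW alone IFI6 (0.16), MMP9 (0.27) and ISG15 (1.08) reversed, none past the threshold. The 2456 genes beyond 2-fold in the mock pair became 453 in the irradiated pair.

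For 10 Gy in Total the 18 calls became 39 with no filter, 46 with a filter at 7 and 6 with the median of probe sets. They became 6 without _x_at and _s_at probe sets and 2 over all 12 arrays. In limma's eBayes without a trend there were 0, where 1146 had an unadjusted p below 0.05. For 10 Gy in HMW minus Total the 3 became 16 with no filter, 1 with a filter at 7, 0 in limma with the median of probe sets (421 with an unadjusted p below 0.05), 1 with loess, 26 without a trend, 65 in HMW minus LMW, where SERPINB3 reversed to -0.082, and 48 in HMW alone.

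Without a test, the 1851 genes beyond 2-fold in WT became 737 in HMW minus LMW. The 57 in the knockdown became 126 with no filter, 27 with a filter at 7, 86 in HMW alone and 135 in LMW alone. The difference between genotypes went from 2076 genes to 1012 in HMW minus LMW and 88 in Total alone, and COL1A1 reversed to 0.41 with the median of probe sets. A gene near the floor in either array gives a compressed difference, which limits what low intensities can show.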

Other observations

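The immediate-early list was written after FOS had been seen, and the test on ribosome loading was chosen after the result.

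FOS was higher in both polysome pools than in Total in every condition. The cells met cycloheximide, warming and trypsin before the polysome lysis, and a candidate explanation is that this handling induced immediate-early genes. Of 44 such genes 36 were measured, and their median difference between polysomes and Total was 0.60, at percentile 100 of random matched lists, whose central 95% ran from -0.31 to 0.32. The difference was above 0 in all 4 conditions for 22 genes and below 0 in all 4 for 4. FOS (3.36), IER2 (1.66), DUSP1 (1.66), EGR1 (1.61) and JUN (1.52) were highest. The list had a median HMW minus LMW difference of -0.302, with 8 of 36 above 0, while the median of all genes was -0.06. This argues against more ribosomes per bound mRNA than on mRNAs in general. Coding length was not examined, so more ribosomes than on other mRNAs of like length stay open. The HMW minus LMW difference also does not read the share of an mRNA that is bound to ribosomes. A larger bound share of these mRNAs therefore stays open. The labels do not say how the total RNA was handled before lysis, so induction by the handling remains a hypothesis.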
